A study of Mus musculus with 20 samples.

How the data were processed

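Total RNA was sequenced from ear pinnae of mice that had received an intradermal injection into the right ear. The injected solution was 10 µl of PBS, or 10 µl of PBS with IL-4, IL-13 or IL-31 at 0.1 µg/µl, per the labels' protocols. There were 4 groups of 5 samples, 20 libraries in all. RNA was purified with a Qiagen RNeasy Plus Universal kit and libraries were made with the NEBNext Ultra II RNA kit, per the labels' protocols. The time from injection to harvest, the aligner, the read counter, the annotation release and whether each sample came from its own animal are not given in the sources used here, so p-values measure the spread between these samples.

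The authors deposited 1 table of log2 CPM values (log2 of read counts scaled to library size) for 16669 genes named by Ensembl identifiers. The build GRCm38 and the tool edgeR, without a version, are named in the submitters' processing notes. The lowest value in the table was -2.684 in every library, which is the log2 of an offset of 0.1556 CPM, so fold changes are on the scale of log2(CPM + offset) and understate the change of low genes. In each library 80.2 to 84.8% of the low values were whole multiples of one step, within 0.02 reads, and that step gives effective library sizes of 6.12 M reads (M, mega; IL-4 library 5) to 23.73 M reads (IL-31 library 4), with a median of 12.98 M. Because the rest of the low values were not whole, no reads were recovered and no count test was run. Linear values summed to between 921691 and 1113112 per library. Gene symbols and coordinates came from GENCODE release M21 for GRCm38, which matched 16644 of the 16669 identifiers.

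The test planned before the data were examined assumed linear values with a pseudocount, and its stated rule for log2 values was followed: limma was run on the values as deposited. Genes with a log2 value of at least 0 in at least 5 of the 20 libraries were kept, which left 16461 and removed 208. One model with the 4 groups was fitted to all 20 libraries (lmFit, contrasts, eBayes with trend), so the groups share an estimate of the spread per gene. A gene was called changed at a two-sided Benjamini-Hochberg adjusted p under 0.05 over the tested genes of its comparison. The 6 comparisons were each cytokine with PBS and each cytokine with each other. R 4.3.3, limma 3.58.1, python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.

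The text names genes by a rule fixed before the data were examined. For each cytokine against PBS it takes the 10 largest rises and 10 largest falls among changed genes whose 5 cytokine values all lay on one side of the 5 PBS values, then members of fixed gene lists, then the receptor genes Il4ra, Il13ra1, Il13ra2, Il2rg, Il31ra and Osmr. Il4, Il13 and Il31, which the rule also names, were not analysed here. The rule gave 103, 109 and 54 genes for IL-4, IL-13 and IL-31, and to hold the text near the planned length 10 list members of smallest adjusted p were taken per comparison, a number set after the rule's genes were seen. That left 36 genes per comparison. Between cytokines, the 5 genes of smallest p are named. Predicted genes and clone names are counted but not named.

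There were 32 gene lists fixed before the data were examined. They cover STAT6 and alternative-activation targets, cytokine receptors, gp130 family and STAT3 targets, chemokines, itch mediators, neurotrophic and axon guidance factors, sensory axon transcripts, Schwann cells, eosinophils, mast cells, basophils, T and innate lymphoid cells, neutrophils, monocytes and macrophages, dendritic cells, B and plasma cells, endothelium, red blood cells, epidermal barrier and stressed keratinocyte genes, extracellular matrix, interferon-stimulated genes, lipid mediators, complement, cell cycle, muscle, cartilage, adipocyte, hair follicle, melanocyte, stress response and mitochondrially encoded genes. The 30 lists with at least 5 tested members were tested with camera in limma at a preset inter-gene correlation of 0.01, and again with the correlation estimated from the data. Benjamini-Hochberg adjustment ran over the 30 lists of a comparison. A list of basal keratinocyte genes was added after the data were seen. A list score is the mean over members of log2 CPM centred per gene.

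The tests were tried on simulated data first. With 200 genes of the 16461 changed in IL-4 against PBS and independent noise, 45.4% of 1.5-fold, 66.6% of 2-fold and 93% of 4-fold changes were recovered, and 5.8% of the calls were false. In the same simulation of IL-4 against IL-13, 44.2%, 66.6% and 91.2% were recovered and 4.4% of the calls were false. With residuals of whole libraries as noise, which keeps genes varying together, IL-4 against PBS gave 44.2%, 69.3% and 90%, with 6.5% false. IL-4 against IL-13 gave 42.4%, 66.9% and 91.5%, with 1.6% false. Each setting had only 5 draws, so the false shares do not give the error of the real calls.

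Alternatives were other pseudocounts and filters, quantile normalization, median-of-ratios rescaling, array quality weights, the 10 samples of a comparison alone, a 2-fold threshold, a replicate block, an estimated inter-gene correlation and each library left out in turn. Others were chosen after seeing the data: a pseudocount of 1, the muscle or barrier list score as a covariate, and PBS libraries 1, 2 and 3 left out together. Because the fold changes of the 3 cytokines share the PBS libraries, unchanged groups were simulated against those controls in 100 draws. The controls were also split into 2 and 3 libraries in 20 ways. A second simulation of 100 draws, chosen after seeing the data, gave each library's residuals from the fit with the muscle score a random sign and fitted the same model again.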

Results

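Gene expression was measured by bulk RNA-seq in mouse ear pinnae after an intradermal injection of PBS or of 1 of 3 cytokines (IL-4, IL-13 and IL-31), with 5 samples per group. IL-4 and IL-13 are type 2 cytokines that signal through Il4ra-containing receptors, and IL-31 is an itch-associated cytokine that signals through Il31ra and Osmr. The series concerns type 2 cytokines, sensory nerves and itch. An ear pinna holds epidermis, dermis, cartilage, hair follicles, fat and muscle, so a value is a mean over all of these tissues. Effective library sizes were 11.3 ± 1.40 M reads in PBS, 10.7 ± 2.96 M in IL-4, 13.3 ± 0.378 M in IL-13 and 16.2 ± 4.29 M in IL-31 (mean ± SD, n = 5). A count of 3 reads corresponds to 0.126 to 0.49 CPM, so differences in genes below that level were not detectable at this depth. Levels are in log2 CPM, fold changes are log2 differences with their standard errors, and adjusted p-values are from limma unless another test is named. Chance figures beside counts of genes with an unadjusted p under 0.05, or without overlap between groups, are averages. Genes vary together across libraries and the spread of such counts was not computed, so an excess alone does not show a difference.

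The comparison of IL-4 with PBS asks which transcripts of the injected skin differ after exposure to IL-4. Retnla, a secreted product of alternatively activated macrophages and a target of STAT6, stood at 3.02 ± 1.35 log2 CPM in IL-4 and at -0.80 ± 1.32 in PBS (SD, n = 5 each), a 14.2-fold rise (log2 fold change 3.83 ± 0.86 SE, limma adjusted p = 0.00583). Genes of the cornifying epidermis rose with it, among them Krt24, a keratin of differentiated epidermis, from 7.09 ± 1.03 to 9.13 ± 0.16 log2 CPM. For Krt24 PBS libraries 1, 2 and 3 were at 6.667, 5.936 and 6.55 and PBS libraries 4 and 5 at 8.454 and 7.856, and without the first 3, an alternative chosen after seeing the data, its log2 fold change was 0.976 (adjusted p = 0.0203) in place of 2.04. Transcripts of skeletal muscle fell, and Myh4, the fast myosin heavy chain IIb, went from 10.08 ± 1.00 to 4.85 ± 2.53 log2 CPM. In all, 2938 genes changed, 1353 higher and 1585 lower, as the bar plot of changed genes shows. Of these, 189 rose and 714 fell by at least 2-fold.

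**Figure D1:**
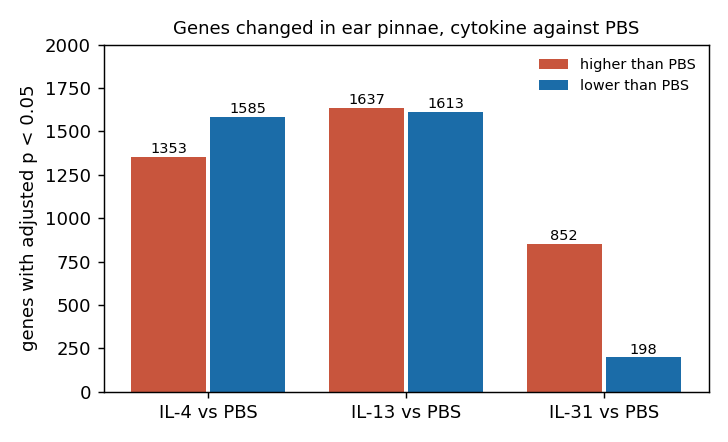
Bars give the number of genes with an adjusted p under 0.05 for each cytokine against PBS, higher in red and lower in blue, with 5 libraries per group. The counts are 1353 and 1585 for IL-4, 1637 and 1613 for IL-13, and 852 and 198 for IL-31.

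Il22ra2, which encodes the soluble decoy receptor for IL-22, rose in IL-4 by 1.13 ± 0.15 on the log2 scale (adjusted p = 0.00051), with all 5 IL-4 libraries above every PBS library. Retnla lies on chromosome 16 from 48842551 to 48844461, Krt24 on chromosome 11 from 99279959 to 99285262, and Il22ra2 on chromosome 10 from 19621998 to 19634681 (GRCm38). All 3 are annotated as protein-coding. The other largest rises among genes whose groups did not overlap, with log2 fold changes from 1.13 to 1.77, were of Rpl36a-ps2, Unc93a2, Lce1d, Nyx, Tgm7, Xkrx and Fam131c. Rpl36a-ps2 is a processed pseudogene and Lce1d belongs to a family of near-identical late cornified envelope genes, so both are uncertain. Without PBS libraries 1, 2 and 3, which stand apart in epidermal genes, the log2 fold changes of Unc93a2, Lce1d, Nyx, Xkrx and Fam131c were 0.428, 0.359, 0.375, 0.535 and 0.777 and that of Rpl36a-ps2 was 1.738, none of which passed, while Tgm7 (1.513) and Il22ra2 (0.799) passed. The call for Fam131c was lost without PBS library 2 (adjusted p = 0.0661). The call for Rpl36a-ps2 was lost without any one of PBS libraries 1 to 4 or IL-4 libraries 2, 3 and 5, and that for Nyx without any one of PBS libraries 1 to 3 or IL-4 libraries 2 to 5.

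All 26 tested members of the skeletal muscle list fell in IL-4, and all 26 also when adjusted over the list alone, with a median log2 fold change of -2.64 (camera adjusted p = 2.12e-21). The adjusted p was 0.404 with an estimated correlation. Mybpc2, Pvalb, Actn3, Myoz1, Ckm, Pygm and Atp2a1, which encode contractile, calcium-handling and energy proteins of muscle fibres, fell by between 2.94 and 5.08. Dhrs7c, Mylk4, Kcna7, Sln and St8sia5, among the largest falls of genes whose groups did not overlap, fell by between 2.95 and 3.74. Muscle-list transcripts took 1.04 to 3.01% of CPM in the PBS libraries and 0.074 to 0.556% in the IL-4 libraries. Of 13 mitochondrially encoded genes 11 fell, and 13 when adjusted over the list alone, with a median of -0.64 (camera adjusted p = 2.1e-07, adjusted p = 0.404 with an estimated correlation). One of them, mt-Nd4, a subunit of respiratory complex I, fell by 0.76 ± 0.17 (adjusted p = 0.00529). The mitochondrial scores of PBS libraries 1, 2 and 3 were 0.402, 0.73 and 0.84, against 0.117 and 0.204 in PBS libraries 4 and 5, and without the first 3 the list median was -0.402 (camera adjusted p = 0.00137) and mt-Nd4 did not pass (-0.461).

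Of 51 tested epidermal barrier and cornified envelope genes, 32 rose in IL-4, none fell and 19 did not pass, and 41 rose and 1 fell when adjusted over the list alone. Their median log2 fold change was 1.14 (camera adjusted p = 7.92e-14, adjusted p = 0.404 with an estimated correlation). Lor, which encodes loricrin, the main protein of the cornified envelope, rose by 2.08 ± 0.57 (adjusted p = 0.0164), and Flg2, which encodes filaggrin 2, by 1.93 ± 0.53 (adjusted p = 0.0179). Without PBS library 2 these adjusted p-values were 0.0501 and 0.0558, and without PBS libraries 1, 2 and 3 the rises were 0.048 and 0.175 and did not pass. The PBS libraries differed among themselves in this list, with scores of -1.012, -1.663 and -1.997 in PBS libraries 1, 2 and 3 and of -0.014 and 0.335 in PBS libraries 4 and 5, against -0.429 to 0.637 in IL-4. The median was 0.10 without PBS libraries 1, 2 and 3 (adjusted p = 0.104). The scores per library are in the plot of gene list scores.

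**Figure D2:**
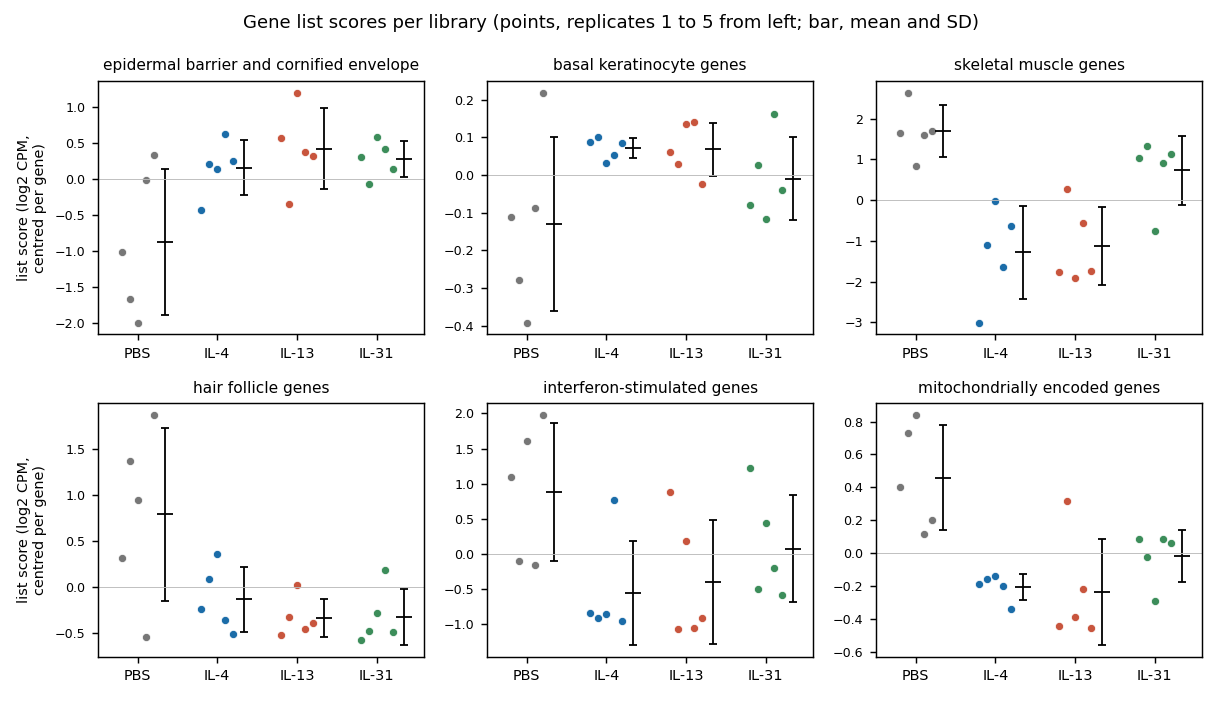
Points are gene list scores of single libraries, in log2 CPM centred per gene, for 6 lists and 4 groups, and bars are group means with SD (n = 5). PBS libraries 1, 2 and 3 have the lowest barrier scores, and the muscle scores of IL-31 library 3 lie below those of the other 4 IL-31 libraries.

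Several immune lists and the vascular list lay lower in IL-4, while lists of T and innate lymphoid cell, mast cell and basophil markers did not pass (camera adjusted p = 0.91, 0.282 and 0.536). Of 34 interferon-stimulated genes 15 fell and none rose, 24 fell when adjusted over the list alone, and the median was -1.42 (camera adjusted p = 1.88e-09, adjusted p = 0.427 with an estimated correlation). The interferon scores were 1.088, 1.61 and 1.979 in PBS libraries 1, 3 and 5 but -0.099 and -0.163 in PBS libraries 2 and 4, and 0.764 in IL-4 library 4 against -0.953 to -0.841 in the other IL-4 libraries. The same libraries stood apart in neutrophil markers, with scores of 2.389, 3.047 and 3.167 in PBS libraries 1, 3 and 5, -0.855 and -1.432 in PBS libraries 2 and 4, 1.808 in IL-4 library 4 and -1.859 to -1.289 in the other IL-4 libraries. Ifi27l2a, an interferon-induced gene, fell by 1.42 ± 0.24 (adjusted p = 0.00139). Of 28 monocyte and macrophage markers 14 fell, 16 when adjusted over the list alone, and the median was -0.98 (camera adjusted p = 2.1e-07, adjusted p = 0.404 with an estimated correlation). PBS library 5 had the highest macrophage score at 1.837, against 0.062 to 0.558 in the other PBS libraries, and IL-4 library 4 was at 0.133 against -0.906 to -0.45 in the other IL-4 libraries; without PBS library 5 the median was -0.704 (camera adjusted p = 0.000184). Of 25 endothelial and lymphatic markers 10 fell, 18 when adjusted over the list alone, and the median was -0.64 (camera adjusted p = 2.1e-07, adjusted p = 0.404 with an estimated correlation). Of 25 dendritic and Langerhans cell markers 1 rose and 4 fell, and 1 and 5 when adjusted over the list alone (camera adjusted p = 0.0144, adjusted p = 0.404 with an estimated correlation). The call for that list was lost without PBS library 2 (adjusted p = 0.0816). Cd40, a costimulatory receptor, fell by 1.61 ± 0.30, and Irf8, a transcription factor of dendritic cells and monocytes, by 1.33 ± 0.22. No member of the macrophage or interferon list rose.

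Of 24 STAT6 and alternative-activation targets 2 rose, Retnla and Cdh1, and 1 fell, the same counts when adjusted over the list alone (camera adjusted p = 0.583). Cdh1, which encodes E-cadherin, rose by 0.69 ± 0.16 (adjusted p = 0.00586). In the cytokine receptor list of 22 genes 2 fell and none rose, also when adjusted over the list alone (camera adjusted p = 0.136). Jak3, the kinase that binds the common gamma chain used by the type I IL-4 receptor, fell by 0.91 ± 0.16 (adjusted p = 0.00145), with all 5 IL-4 libraries below every PBS library. Of 48 neurotrophic and axon guidance genes 8 rose and 4 fell, 9 and 5 when adjusted over the list alone (camera adjusted p = 0.91). Robo2, an axon guidance receptor, rose by 0.77 ± 0.12 (adjusted p = 0.00107), while Vegfa, a growth factor for vessels, fell by 1.21 ± 0.20 (adjusted p = 0.00133) and its coreceptor Nrp1 by 0.99 ± 0.19 (adjusted p = 0.00234). Of 8 sensory axon transcripts 3 fell, also when adjusted over the list alone (camera adjusted p = 0.0231, adjusted p = 0.404 with an estimated correlation). Gap43, a protein of growing axons, fell by 1.30 ± 0.24 (adjusted p = 0.00185), and the list's call was lost without PBS library 5 (adjusted p = 0.0632). The same list did not pass in IL-13, with 3 genes lower (camera adjusted p = 0.123), or in IL-31, with none (camera adjusted p = 0.553). Hspa1a, a heat shock protein, rose by 0.68 ± 0.13.

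In the IL-4 comparison 1404 of 16461 tested genes (8.53%) had no overlap between the 5 IL-4 and 5 PBS libraries, where chance gives 0.79%. The count of 2938 was 1885 without PBS library 2, 1956 without IL-4 library 5, 1200 without PBS libraries 1, 2 and 3, 1269 when only the 10 libraries compared were fitted, and 3 with the muscle list score as a covariate, and after quantile normalization 59.5% of changed genes were higher in place of 46.1%. With the barrier list score as a covariate 1327 of the 2938 genes were still called.

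**Figure D3:**
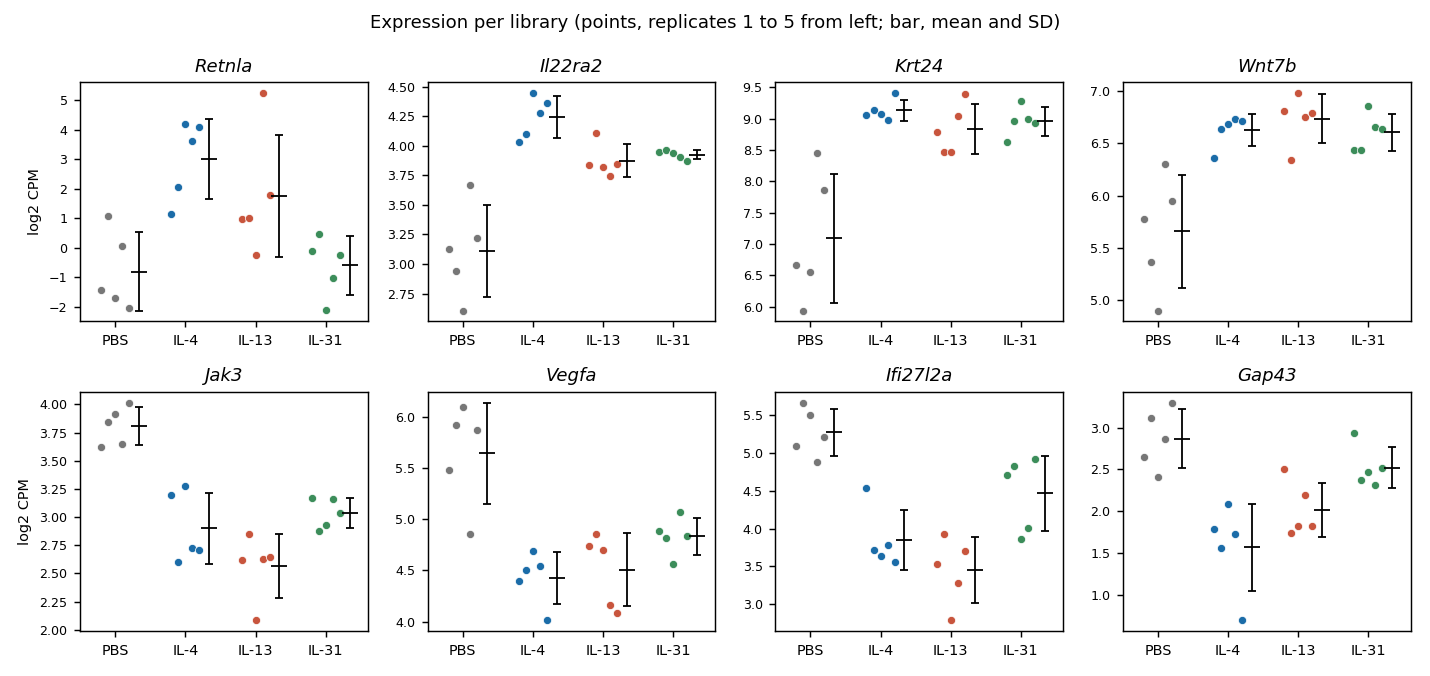
Points are log2 CPM values of single libraries for 8 named genes, in the order of replicates 1 to 5 from left, and bars are group means with SD (n = 5). All 5 IL-4 libraries lie above every PBS library for Retnla, Il22ra2, Krt24 and Wnt7b, and below them for Jak3, Vegfa, Ifi27l2a and Gap43.

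The comparison of IL-13 with PBS puts the same question for IL-13, which shares receptor chains with IL-4. Epidermal genes rose here too, with Krt24 at 8.83 ± 0.40 log2 CPM against 7.09 ± 1.03 in PBS (log2 fold change 1.74 ± 0.33, adjusted p = 0.00228), or 0.677 without PBS libraries 1, 2 and 3 (adjusted p = 0.0949). Clca1, a secreted protein of mucus-producing epithelia, rose from 1.15 ± 0.40 to 2.49 ± 0.66 (1.33 ± 0.28, adjusted p = 0.00342), and Wnt7b, a secreted Wnt ligand, from 5.66 ± 0.54 to 6.73 ± 0.24 (1.07 ± 0.19, adjusted p = 0.00172). Without the same 3 PBS libraries Clca1 was at 1.048 (adjusted p = 0.105) and Wnt7b at 0.607 (adjusted p = 0.0466). Muscle transcripts fell, with Myh4 at 5.72 ± 1.86 against 10.08 ± 1.00 (-4.36 ± 0.96, adjusted p = 0.00479). In all, 3250 genes changed, 1637 higher and 1613 lower, of which 281 and 673 changed by at least 2-fold.

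Retnla was at 2.56 ± 0.86 above PBS on the log2 scale (adjusted p = 0.0412), with IL-13 libraries at 0.98, 1.01, -0.24, 5.24 and 1.79 log2 CPM, and its call was lost without any one of PBS libraries 1, 3 and 5 or IL-13 libraries 4 and 5. The groups overlapped, as the PBS libraries were at -2.051 to 1.088. Among genes whose groups did not overlap, the largest rises besides those of Krt24, Clca1 and Wnt7b were of Adnp, Unc93a2, Bspry, Nyx, Rps27, Gpr37 and Add2, with log2 fold changes from 1.10 to 2.53. Their log2 fold changes were 0.581, 0.483, 0.82, 0.343, 0.412, 0.854 and 1.121 in that order without PBS libraries 1, 2 and 3, and none passed. Adnp ranged from -2.68, the lowest value in the table, to 2.44 log2 CPM across the PBS libraries. Rps27, a ribosomal protein gene with processed copies elsewhere in the genome, is uncertain, and its call was lost without any one of PBS libraries 1 to 3 or IL-13 library 3. The call for Nyx was lost without any one of PBS libraries 1 to 3 or IL-13 libraries 1, 3, 4 and 5. Wnt7b lies on chromosome 15 from 85535437 to 85582473, Clca1 on chromosome 3 from 145003817 to 145032776 and Myh4 on chromosome 11 from 67238029 to 67260446 (GRCm38).

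Of the 51 barrier genes 40 rose in IL-13, none fell and 11 did not pass, and 44 rose when adjusted over the list alone, with a median of 1.38 (camera adjusted p = 3.44e-17, adjusted p = 0.5 with an estimated correlation). Lor rose by 2.47 ± 0.57 (adjusted p = 0.00598), Krt10, the main keratin of suprabasal epidermis, by 2.00 ± 0.51 (adjusted p = 0.0108), and Flg2 by 1.97 ± 0.53 (adjusted p = 0.0145). The IL-13 libraries had barrier scores of -0.349 to 1.207, and without PBS libraries 1, 2 and 3, which had the lowest scores, the list median was 0.27 (adjusted p = 0.000168), and the rises of Lor, Krt10 and Flg2 were 0.437, 0.311 and 0.219 and did not pass. Of 18 hair follicle genes 5 rose and 6 fell, 5 and 9 when adjusted over the list alone (camera adjusted p = 0.241). Krt35, a hair shaft keratin, fell by 4.37 ± 0.96 (adjusted p = 0.00486), with overlapping groups: the PBS libraries were at 0.849, 4.501, 3.084, -2.039 and 4.816 log2 CPM and the IL-13 libraries at -2.684 to -0.888. Its log2 fold change was -5.441 without PBS library 4, and -3.517 without PBS libraries 1, 2 and 3, where it did not pass. Of 26 immediate early and heat shock genes 4 rose and 1 fell, 6 and 1 when adjusted over the list alone (camera adjusted p = 0.934), and Hspa1b rose by 0.96 ± 0.19 and Hspa1a by 0.71 ± 0.13. Erbb3, a receptor of Schwann cells that epidermis also expresses, rose by 0.42 ± 0.09, and of the 25 Schwann cell markers 2 rose and 2 fell, also when adjusted over the list alone (camera adjusted p = 0.224).

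All 26 muscle genes fell in IL-13, also when adjusted over the list alone, with a median of -2.60 (camera adjusted p = 3.38e-19, adjusted p = 0.5 with an estimated correlation). Muscle-list transcripts took 0.166 to 0.614% of CPM in IL-13 libraries. Among genes whose groups did not overlap, the largest named falls after Myh4 were of Mylk4, Dhrs7c, Tmem233, Myoz1, Pygm, Ckm, Lrrc30, Nos1 and Atp2a1, by between 3.00 and 3.39. Mybpc2, Pvalb and Actn3, whose groups overlapped, fell by between 3.66 and 4.49. Of 13 mitochondrially encoded genes 11 fell, 13 when adjusted over the list alone, with a median of -0.67 (camera adjusted p = 2.52e-07, adjusted p = 0.5 with an estimated correlation), and mt-Nd2 fell by 0.81 ± 0.18. That median was -0.441 without PBS libraries 1, 2 and 3 (camera adjusted p = 0.000106) and mt-Nd2 did not pass (-0.578). Of 34 interferon-stimulated genes 11 fell, 13 when adjusted over the list alone, with a median of -1.24 (camera adjusted p = 1.59e-07, adjusted p = 0.545 with an estimated correlation), and Ifi27l2a fell by 1.82 ± 0.24 (adjusted p = 0.000938). IL-13 libraries 1 and 3 had interferon scores of 0.877 and 0.183 and neutrophil scores of 2.916 and 1.734, and the other IL-13 libraries had interferon scores of -1.077 to -0.914 and neutrophil scores of -2.264 to -1.607. Of 28 monocyte and macrophage markers 8 fell, 9 when adjusted over the list alone, with a median of -0.79, or -0.534 without PBS library 5 (camera adjusted p = 6.31e-05 and 0.0153, and adjusted p = 0.545 with an estimated correlation). Of 25 endothelial markers 12 fell, 18 when adjusted over the list alone (camera adjusted p = 2.31e-06, adjusted p = 0.5 with an estimated correlation). Of 25 adipocyte genes 1 rose and 6 fell, 2 and 11 when adjusted over the list alone (camera adjusted p = 0.024, adjusted p = 0.722 with an estimated correlation). Car3, a carbonic anhydrase abundant in fat and muscle, fell by 1.69 ± 0.34 (adjusted p = 0.003). The adipocyte call was lost without any one of PBS libraries 2, 3 and 4 or IL-13 libraries 3 and 4.

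Jak3 fell by 1.25 ± 0.16 in IL-13 (adjusted p = 0.00085) and Vegfa by 1.14 ± 0.20 (adjusted p = 0.00193). Cdh1 rose by 0.75 ± 0.16, and in the STAT6 list 2 genes rose and 3 fell, 3 and 3 when adjusted over the list alone (camera adjusted p = 0.657). In all, 1238 tested genes (7.52%) had no overlap between the 5 IL-13 and 5 PBS libraries, where chance gives 0.79%. The count of 3250 was 1995 without PBS library 2, 2022 without IL-13 library 3, 385 without PBS libraries 1, 2 and 3, 1134 when only the 10 libraries compared were fitted, 1 with the muscle list score and 168 with the barrier list score as a covariate, and after quantile normalization 61.4% of changed genes were higher in place of 50.4%.

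The comparison of IL-31 with PBS asks what an itch-associated cytokine does to the same tissue. Most changed genes were higher, and epidermal genes were among the larger rises. Krt10 stood at 14.06 ± 0.24 log2 CPM in IL-31 and at 12.01 ± 1.55 in PBS (log2 fold change 2.05 ± 0.51, adjusted p = 0.0273), and Flg2 at 10.23 ± 0.17 against 8.01 ± 1.71 (2.21 ± 0.53, adjusted p = 0.0245). Slurp1 and Slurp2, secreted epidermal proteins of the Ly6 family, rose by 2.11 ± 0.48 and 2.52 ± 0.56. Nrtn, which encodes the neurotrophic factor neurturin, rose from 4.07 ± 1.25 to 5.71 ± 0.33 (1.65 ± 0.38, adjusted p = 0.0223), with PBS libraries 1, 2 and 3 at 2.821, 2.762 and 4.16 and PBS libraries 4 and 5 at 5.232 and 5.356. Without PBS libraries 1, 2 and 3 the rises of Krt10, Flg2, Slurp1, Slurp2 and Nrtn were 0.361, 0.462, 0.506, 0.657 and 0.42, and none passed. In all, 1050 genes changed, 852 higher and 198 lower, of which 203 and 20 changed by at least 2-fold.

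Cldn23, Serpina12, Dkkl1, Krt24, Fam89a and Orm1 completed the 10 largest rises among genes whose groups did not overlap, with log2 fold changes from 1.75 to 2.33. These were 0.564, 0.514, 0.679, 0.802, 0.636 and 0.397 without PBS libraries 1, 2 and 3, and none passed. Of the 51 barrier genes 32 rose, none fell and 19 did not pass, and 41 rose and 1 fell when adjusted over the list alone, with a median of 1.32 (camera adjusted p = 3.31e-19, adjusted p = 0.975 with an estimated correlation). Lor rose by 2.43 ± 0.57 (adjusted p = 0.0223). The IL-31 libraries had barrier scores of -0.061 to 0.583, and without PBS libraries 1, 2 and 3 the list median was 0.24 (adjusted p = 0.000213). Of 26 lipid mediator genes 3 rose and none fell, 5 and none when adjusted over the list alone (camera adjusted p = 0.694). They include the epidermal lipoxygenases Alox12, with a rise of 1.66 ± 0.36, and Alox12e, with 1.29 ± 0.30, or 0.5 and 0.518 without PBS libraries 1, 2 and 3, where neither passed. In the neurotrophic and axon guidance list 3 of 48 rose and 1 fell, also when adjusted over the list alone (camera adjusted p = 0.694). Robo2 rose by 0.52 ± 0.12 and Vegfa fell by 0.81 ± 0.20. Of 26 immediate early and heat shock genes 3 rose, Hspa1a, Hspa1b and Dnajb1, by 0.65 to 0.84, also when adjusted over the list alone (camera adjusted p = 0.819).

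Among genes that passed and whose groups did not overlap, the largest named falls in IL-31 were of Slc2a4rg-ps, Rnf122, mt-Nd3, Zdhhc12, Ankle1, Fbxl22, Sfxn4, Tha1, Usp35 and Dysf, by between 0.87 and 1.17, and Slc2a4rg-ps is annotated as a pseudogene and is uncertain. Krt35, whose groups overlapped, fell further, by 3.83 ± 0.96 (adjusted p = 0.0273), with PBS library 4 among the IL-31 values. Rnf122, which encodes an E3 ubiquitin ligase, lies on chromosome 8 from 31111820 to 31131482 and Krt10 on chromosome 11 from 99385254 to 99389364 (GRCm38). Jak3 fell by 0.78 ± 0.16 (adjusted p = 0.0193). None of the 26 genes of the muscle list passed in IL-31, also when adjusted over the list alone. The list median was -0.89 (camera adjusted p = 0.000131, adjusted p = 0.975 with an estimated correlation), and Myh4 was at -2.04 ± 0.96 (adjusted p = 0.203). Without IL-31 library 3, the lowest of its group in muscle transcripts, the muscle list median was -0.552 (camera adjusted p = 0.0125). Muscle-list transcripts took 0.32 to 1.41% of CPM in the IL-31 libraries. No interferon-stimulated gene passed, and the list median was -0.75 (camera adjusted p = 0.000286, adjusted p = 0.975 with an estimated correlation). The interferon call was lost without PBS library 5 (adjusted p = 0.0998). Of 13 mitochondrially encoded genes 2 fell, 10 when adjusted over the list alone, with a median of -0.47 (camera adjusted p = 3.76e-05, adjusted p = 0.975 with an estimated correlation), or -0.161 without PBS libraries 1, 2 and 3 (camera adjusted p = 0.0318).

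In the IL-31 comparison 718 tested genes (4.36%) had no overlap between the 5 IL-31 and 5 PBS libraries, where chance gives 0.79%. The call of each gene named as changed in IL-31 was lost in 4 to 9 of the 10 fits that left out 1 library. The count of 1050 was 26, 0, 1, 1885 and 3029 without PBS libraries 1 to 5 in that order, 498, 0, 405 and 0 without IL-31 libraries 1, 3, 4 and 5, and 0 without PBS libraries 1, 2 and 3, when only the 10 libraries compared were fitted by limma, and with the muscle or the barrier list score as a covariate. In the fits with 0 genes, 1227 to 3427 had an unadjusted p under 0.05, where chance gives 823 on average, with a spread that was not computed.

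The 6 receptor genes did not pass in any of the 3 comparisons with PBS, as the plot of receptor genes shows. Il4ra was at 5.10 ± 1.07 log2 CPM in PBS, 4.55 ± 0.21 in IL-4, 4.86 ± 0.62 in IL-13 and 4.96 ± 0.44 in IL-31 (SD, n = 5). Osmr, a chain of the IL-31 receptor, was at 5.24 ± 0.37 in PBS and 4.96 ± 0.29 in IL-31 (adjusted p = 0.339). Il31ra was at -0.25 ± 1.59 in PBS and -0.03 ± 0.39 in IL-31 (adjusted p = 0.818). Il2rg, the common gamma chain, differed from PBS by -0.70 ± 0.26 in IL-13 (adjusted p = 0.0615). Il13ra1 was at 0.50 ± 0.25 and Il13ra2 at -0.16 ± 0.33 relative to PBS in IL-13 (adjusted p = 0.163 and 0.763).

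**Figure D4:**
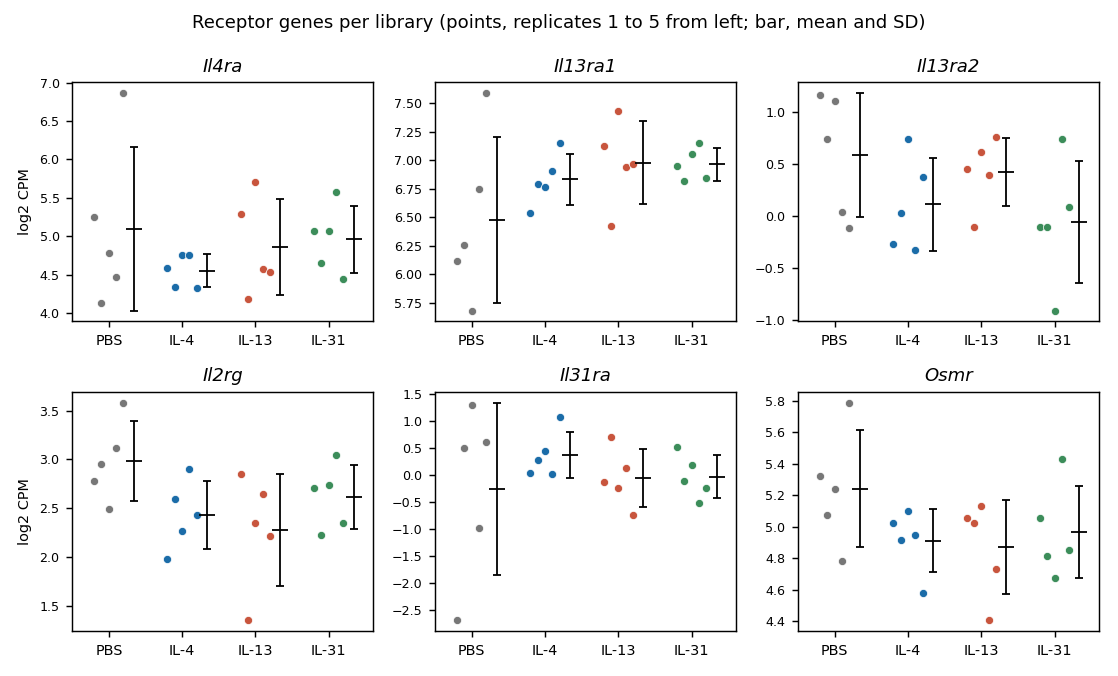
Points are log2 CPM values of single libraries for the 6 receptor genes, in the order of replicates 1 to 5 from left, and bars are group means with SD (n = 5). The 4 groups overlap for each gene, and PBS library 5 has the highest Il4ra value.

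The changed genes of IL-4 and IL-13 overlapped in 2232 genes, 1053 higher in both and 1179 lower in both, where independent lists would share 134.6 and 155.3. None of them went in opposite directions. IL-4 and IL-31 shared 829 changed genes (703 higher, 126 lower, with 70 and 19.1 from independent lists), and IL-13 and IL-31 shared 944 (800 and 144, with 84.7 and 19.4). Krt24, Il22ra2, Wnt7b, Robo2 and Jak3 changed in the same direction in all 3 comparisons. Across the 16461 tested genes, which are not independent replicates, fold changes of IL-4 and IL-13 correlated with r = 0.888 (Spearman rho = 0.841), IL-4 and IL-31 with r = 0.768 (0.775), and IL-13 and IL-31 with r = 0.811 (0.838). All of these share the 5 PBS libraries. Unchanged groups simulated against them gave a mean r of 0.665, from 0.011 to 0.922 over 100 draws, and a mean overlap of 17.6 genes, with 937 at most. They gave the same sign in 76.2% of genes on average and in 88% at most, against 83.4, 80.4 and 84.8% observed. The observed r, the shares of the same sign and the overlap of IL-4 and IL-31 thus lay within the simulated range. The overlaps of the other pairs lay above it.

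The covariances of fold changes were 0.298 for IL-4 and IL-13, 0.193 for IL-4 and IL-31 and 0.203 for IL-13 and IL-31, against a mean of 0.0695 and a maximum of 0.16 for simulated unchanged groups, which leaves 0.228, 0.123 and 0.133 above the simulated mean. With separate PBS libraries for each cytokine, 2 for one and 3 for the other, r averaged 0.596, 0.426 and 0.455 and the covariance 0.234, 0.129 and 0.139 over 20 splits, and the shared changed genes had medians of 615, 12.5 and 6 (0 to 820, 0 to 288 and 0 to 366). The overlap of IL-4 and IL-13 was 1306 without PBS library 2 and 348 without PBS libraries 1, 2 and 3, and both overlaps with IL-31 were 0 without PBS library 2 or IL-31 library 3 or 5, and 1833 (IL-4) and 2510 (IL-13) without PBS library 5. Muscle genes lay near the diagonal for IL-4 and IL-13 and off it for IL-4 and IL-31 in the plot of fold changes, with Ckm at -3.27 in IL-4, -3.03 in IL-13 and -1.11 in IL-31.

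**Figure D5:**
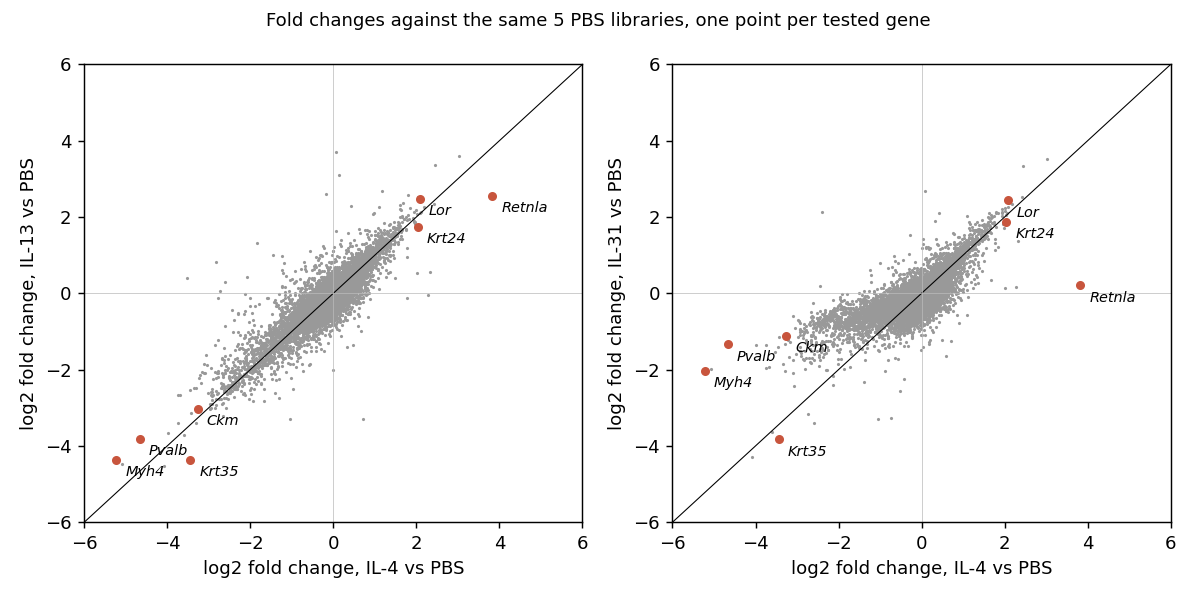
Each point is 1 of the 16461 tested genes, with its log2 fold change against PBS in IL-4 on the x axis and in IL-13 (left) or IL-31 (right) on the y axis, and the line marks equal values. Lor and Krt24 lie near the line in both panels, Retnla lies at 3.83 against 2.56 and 0.21, and Myh4, Pvalb and Ckm lie above the line in the right panel.

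No gene differed between IL-4 and IL-13 by limma, where 664 genes had an unadjusted p under 0.05 and chance gives 823. The smallest adjusted p was 0.997. Retnla, at 3.02 ± 1.35 and 1.76 ± 2.08 log2 CPM, was among the genes that did not pass. The genes of smallest p were Dnlz at -0.44 ± 0.10 in IL-4 relative to IL-13, Kifc1, a mitotic kinesin, at -0.55 ± 0.13, Acat3 at 1.32 ± 0.31, Slc16a4 at 0.96 ± 0.24 and Pus3 at 0.40 ± 0.10, none of which passed. The cell cycle list of 35 genes lay lower in IL-4 with a median of -0.41 and no member past the threshold, also when adjusted over the list alone (camera adjusted p = 2.45e-21, adjusted p = 0.956 with an estimated correlation). IL-13 libraries 1 and 3 had cell cycle scores of 0.772 and 0.486, and the other IL-13 libraries, at -0.166 to 0.13, lay within the IL-4 range of -0.408 to 0.174. The median was -0.266 without IL-13 library 1. The list of 31 stressed and hyperproliferative keratinocyte genes had a median of -1.11 and no member past the threshold (camera adjusted p = 2.82e-05, adjusted p = 0.956 with an estimated correlation). Its scores were 2.16 and 3.527 in the same 2 IL-13 libraries and -1.609, -0.295 and -0.864 in the others, within the IL-4 range of -1.643 to 0.841, and the call was lost without IL-13 library 3 (median -0.318, adjusted p = 0.204). The groups did not overlap for 0.81% of genes, where chance gives 0.79%.

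No gene differed between IL-4 and IL-31 by limma, where 1743 genes had an unadjusted p under 0.05 and chance gives 823, and the smallest adjusted p was 0.142. Asb15, a muscle-enriched gene, was at -2.37 ± 0.41 in IL-4 relative to IL-31 and Mybph, a myosin-binding protein, at -2.62 ± 0.53. Retnla was at 3.62 ± 0.86 (adjusted p = 0.174). Rhoc was at -0.61 ± 0.11, Atp5g1 at -0.52 ± 0.10 and Slc47a1 at -1.57 ± 0.34, and none of these passed. The median of the 26 muscle genes was -1.81, all 26 fell when adjusted over the list alone, and none over all genes tested (camera adjusted p = 3.41e-28, adjusted p = 0.165 with an estimated correlation). The endothelial list had a median of -0.47, with 3 of 25 lower when adjusted over the list alone (camera adjusted p = 1.71e-10, adjusted p = 0.246 with an estimated correlation). Without IL-31 library 3, which has the lowest muscle score of its group at -0.756, 304 genes differed, and with array quality weights 692.

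No gene differed between IL-13 and IL-31 by limma, where 1200 genes had an unadjusted p under 0.05 and chance gives 823, and the smallest adjusted p was 0.215. Lrrc2 was at -1.97 ± 0.37 in IL-13 relative to IL-31, Casq2, a calcium-binding protein of muscle, at -1.83 ± 0.38, Mlf1 at -1.50 ± 0.31, Foxp2 at -1.06 ± 0.22 and Afap1l1 at -0.91 ± 0.18, and none of these passed. The median of the muscle list was -1.87, and again all 26 fell when adjusted over the list alone and none over all genes tested (camera adjusted p = 4.45e-34, adjusted p = 0.142 with an estimated correlation). The cell cycle list had a median of 0.31 with no member past the threshold (camera adjusted p = 2.72e-11, adjusted p = 0.476 with an estimated correlation), and 0.184 without IL-13 library 1. The complement list had a median of -0.54, with 1 of 22 lower when adjusted over the list alone (camera adjusted p = 1.4e-07, adjusted p = 0.26 with an estimated correlation). Without IL-31 library 3, 297 genes differed, and with array quality weights 535.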

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

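The tests of a fall in muscle transcripts as a cause of relatively more epidermal reads, of more epidermis in every layer, of 3 PBS libraries alone, of library size and of the shared PBS libraries were chosen after the results were seen. So were the muscle score as a covariate and the simulation beside it, though the bound of 0.75 for that covariate test was set before its value was seen. For the test of less muscle in the pieces taken and for the splits, the bounds were also set before their values were seen. Groups of 5 libraries were searched for a library far from the other 4, with a gap to the nearest of them above 0.71 of the group's range. This marked 29 of 444 groups tested, and chance marks about 1 in 20 groups (22.2), so single marks carry little weight. Of the marks, 9 are in IL-31 library 3 and 7 in IL-4 library 1.

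IL-31 library 3 was the lowest of its group in muscle transcripts, at 2.425 log2 CPM for Mylk4, 3.275 for Myoz1, 0.6705 for Dhrs7c, 6.674 for Ckm, 5.324 for Pygm, 0.9779 for Kcna7 and 8.187 for Atp2a1, with a muscle list score of -0.756 and a mitochondrially encoded gene score of -0.289. IL-4 library 1 was the lowest of its group for Sln at 0.77, Wnt7b at 6.363, Hspa1b at 8.141 and Krt10 at 12.97, and the highest for Ifi27l2a at 4.536, mt-Nd3 at 7.926 and Zdhhc12 at 2.293 log2 CPM. IL-4 library 4 was the highest of its group for Irf8 at 3.295 log2 CPM and in the scores of itch mediators at 0.516, neutrophil markers at 1.808 and interferon-stimulated genes at 0.764. PBS library 5 was the highest of its group in the scores of cytokine receptors at 0.713, monocyte and macrophage markers at 1.837 and extracellular matrix genes at 1.087. IL-13 library 2 was the highest of its group for Il22ra2 at 4.111 and mt-Nd4 at 11.13 and the lowest for Krt10 at 13.02 log2 CPM. IL-13 library 1 held Rpl36a-ps2 at -2.684, the lowest value in the table. IL-31 library 4 was the largest of its group at 23.73 M reads, with a score of T and innate lymphoid cell markers of 0.558.

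Epidermal barrier genes were higher with each cytokine than with PBS. Lost muscle transcripts would raise every other gene alike, but the median log2 fold change of all other tested genes in IL-4 was -0.015 against 1.14 for the barrier list. Normalization to library size can hold that median near 0, so it decides little. Muscle-list transcripts took on average 1.8% of CPM in PBS and 0.322% in IL-4. That share is too small to free reads for a rise of 1.14, which argues against this explanation. More epidermis of every layer would raise basal keratinocyte genes as well, but barrier scores exceeded basal scores by 0.987 more in the 15 cytokine libraries than in the 5 PBS libraries (two-sided exact permutation p = 0.00284). That difference lies in PBS libraries 1, 2 and 3, at -0.901, -1.385 and -1.604, since PBS libraries 4 and 5, at 0.073 and 0.116, were within the cytokine range of -0.517 to 1.071, and without those 3 libraries it was 0.152 (exact permutation p = 0.559). So it argues only against an equal loss of every layer of epidermis as all that sets those 3 libraries apart. Their basal scores were -0.111, -0.278 and -0.393, against -0.118 to 0.163 in the cytokine libraries. Less epidermis as part of what sets them apart therefore stays open. The third explanation stays open: without PBS libraries 1, 2 and 3 the list medians were at most 0.271 and at least 0.095, so those 3 libraries may carry most of the difference. A cytokine effect on keratinocyte differentiation also stays open and was not tested apart from the PBS libraries.

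Skeletal muscle genes were lower with IL-4 and IL-13 than with PBS. A difference in library size is argued against, since the IL-31 libraries were the largest and their muscle median was -0.889 against -2.643 in IL-4. Across the 26 muscle genes, which are not independent replicates, the fall correlated with the slope on the muscle score within groups at r = 0.911 (Spearman rho 0.815), so less muscle in the pieces of ear taken may account for the fall. An effect of IL-4 and IL-13 on muscle fibres of the ear was not tested and stays open.

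The fold changes of the 3 cytokines against PBS resembled one another. Chance values of the shared PBS libraries are argued against as the whole cause, because with separate PBS libraries the lowest covariance over 20 splits and 3 pairs stayed above 0 at 0.0547, and the smallest observed covariance was 1.205 times the highest simulated one. The observed r and shares of the same sign lay within the simulated range, so they do not add to this. For muscle content, the score was fitted as a covariate and the muscle genes were left out. The covariance of IL-13 and IL-31 was then 1.31 times that without the covariate, over the bound of 0.75. The covariate also raised the mean covariance of simulated unchanged groups for this pair, from 0.064 to 0.103, so the ratio alone decides nothing. The covariate raised the median standard error in IL-13 1.553 times, so 100 draws were simulated with muscle content as the only difference and the same covariate fitted. For IL-13 and IL-31 their covariances averaged 0.103 against 0.26 observed, and 1 of 100 was as large (highest 0.266). For IL-4 with IL-13 and with IL-31 none was (0.44 and 0.266 observed, highest simulated 0.422 and 0.255). The observed values lay near the upper edge of the draws, which take the score as an exact and linear measure of muscle. Only on that assumption do they argue against muscle content as the whole cause. Muscle content as part of the cause stays open, as the covariate lowered the fold changes in IL-4 and IL-13. A response common to the 3 cytokines, one to injected protein against PBS alone, and a difference of the PBS pieces in other tissues than muscle also stay open and were not tested.

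Splits of the 10 libraries of each comparison into other groups of 5 were drawn 100 times, the real split included. For the overlap of IL-4 and IL-13 the labels of all PBS, IL-4 and IL-13 libraries were shuffled together instead. For IL-4 against PBS (2938, highest other split 2314) and IL-31 against PBS (1050, highest other 348) only 1 split, the real one, was as large. This argues against a chance division of the libraries, but the IL-31 count was 0 without PBS library 2. For the overlap of IL-4 and IL-13 (2232, highest other 0, 1 split as large) shuffled labels mix PBS with cytokine libraries, so few genes are called at all. They cannot say whether the shared PBS libraries give the overlap. Simulated unchanged groups against those libraries shared up to 937 genes. For IL-13 against PBS 2 of the 100 splits gave at least 3250 genes. The other one gave 5266, more than the real split, with PBS libraries 1 to 4 and IL-13 library 2 on one side. This points to a structure of the samples beyond the groups, so the splits do not exclude chance there. For IL-4 against IL-13, IL-4 against IL-31 and IL-13 against IL-31 the real count is 0, which all 100 splits match by necessity, so the splits say nothing about chance there, and the highest others were 1, 158 and 464. The last of these had IL-13 libraries 1, 3, 4 and 5 with IL-31 library 3 on one side, and the one of 158 had IL-4 libraries 1, 3, 4 and 5 with IL-31 library 3, which points to a structure of the samples beyond the groups. Chance cannot be excluded for the number of gene lists past the threshold at the preset correlation. As many lists came from 42 splits for IL-4 against PBS (13, highest other 19), 52 for IL-13 (13, highest other 19), 100 for IL-31 (4, highest other 18), 90 for IL-4 against IL-13 (6, highest other 16), 25 for IL-4 against IL-31 (13, highest other 19) and 41 for IL-13 against IL-31 (12, highest other 19).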

How the results depend on the processing

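The fits with a pseudocount of 1, with the muscle or barrier score as a covariate and without PBS libraries 1, 2 and 3 were chosen after seeing the data, and the others before. Counts for IL-4, IL-13 and IL-31 against PBS were 2938, 3250 and 1050, and their overlaps 2232 (IL-4 and IL-13), 829 (IL-4 and IL-31) and 944 (IL-13 and IL-31). They stayed within 1.5 times of that under other pseudocounts, filters, quantile normalization and median-of-ratios rescaling. The edgeR, DESeq2 and voom alternatives were not run, because the values are not counts.

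With only the 10 samples compared the counts were 1269, 1134 and 0, the overlaps 817, 0 and 0, and IL-4 against IL-31 gave 3, with fewer samples behind each spread. At a 2-fold threshold they were 903, 954 and 223, and the overlaps 684, 146 and 183. Array quality weights gave 1667 for IL-31, 1438 for its overlap with IL-13, 692 for IL-4 against IL-31 and 535 for IL-13 against IL-31, and the cause was not tested. Without PBS libraries 1, 2 and 3 the counts were 1200, 385 and 0 and the overlaps 348, 0 and 0, with fewer samples. In that fit the cell cycle list in IL-31 turned to -0.241, Krt10 in IL-4 to -0.026 and Nrtn in IL-4 to -0.068, and the cause was not tested. Of 237 tests of named genes against PBS 137 lost their call in that fit and 98 kept their result. So rises and falls given without it, such as those of Cdh1 and the heat shock genes, may depend on those PBS libraries too.

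The muscle score as a covariate left 3, 1 and 0 genes and overlaps of 1, 0 and 0. For the genes called in IL-4, it moved the median absolute log2 fold change from 0.675 to 0.426 and the median standard error from 0.173 to 0.262, and in IL-13 from 0.671 to 0.411 and from 0.172 to 0.255, so calls ended through both. In IL-31 the medians were 0.617 and 0.586, with standard errors of 0.152 and 0.162. With the barrier score 168 genes were called in IL-13, and 119 of the 3250 called without it were still called. In IL-31 it left 0 genes, with a median of 0.283, and the overlaps were 166, 0 and 0. In IL-4 1327 of the 2938 called genes were still called with it, with a median absolute log2 fold change of 0.475 in place of 0.675. Covariates were not used on lists or named genes, since a list cannot be tested given its own score.

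With 1 library left out, the counts ranged from 1885 to 3553 in IL-4, 1995 to 4703 in IL-13, 0 to 3029 in IL-31, 0 to 304 in IL-4 against IL-31, 0 to 297 in IL-13 against IL-31 and 0 to 0 in IL-4 against IL-13. The overlaps ranged from 1306 to 2936, 0 to 1833 and 0 to 2510. The muscle list median in IL-4 against IL-13 was -0.311 without IL-4 library 3 (camera adjusted p = 0.009). It turned to 0.353 without IL-4 library 1 (camera adjusted p = 0.00502). Camera at the preset correlation thus passed in opposite directions depending on a single library. Of 180 list tests 61 passed, 58 to 76 with 1 library left out, and 0 with an estimated inter-gene correlation, which widens each test. The estimated correlation was 0.857 for the muscle, 0.668 for the barrier and 0.659 for the interferon list, against the preset 0.01. Small camera p-values at the preset therefore overstate the evidence for such lists.

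With the replicate number as a block the counts were 2952, 3252 and 1247, and IL-4 against IL-31 gave 2, the one count that moved past 1.5 times. The numbers do not pair the samples in general: 30 same-numbered pairs had a mean correlation of 0.029 (from -0.236 to 0.486, 10 over 0.1), and 3 of 20 samples correlated best with their own number. PBS library 2 correlated with IL-13 library 2 at 0.486 and with IL-31 library 2 at 0.452, and those 2 with each other at 0.402. IL-4 library 2 was at 0.029 to 0.078 with these libraries. A shared origin of libraries numbered 2 was not tested and stays open. Depth limits low genes most, since 3 reads are 0.49 CPM in the smallest library and 0.126 in the largest.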

Other observations

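The tests named in this part were planned on lists fixed before the data were examined, except the basal keratinocyte list, which was chosen after the data were seen. Neutrophil markers had medians of -2.41, -1.75 and -1.46 in IL-4, IL-13 and IL-31 against PBS, and none of the 19 members passed in any of the 3 comparisons (camera adjusted p = 0.00238, 0.0839 and 0.0561, and adjusted p = 0.755, 0.815 and 0.975 with an estimated correlation). These transcripts took 0.0113 to 0.205% of CPM across the PBS libraries and 0.0081 to 0.117% across the IL-13 libraries. With 1 library left out their IL-13 median ranged from -2.688 (without IL-13 library 1, camera adjusted p = 0.00259) to -1.144. The IL-31 median ranged from -2.227 (without PBS library 4, camera adjusted p = 0.00628) to -0.742, so both outcomes hang on single libraries. Of 22 complement genes 10 fell in IL-4 and 1 rose and 9 fell in IL-13, 13 and 9 fell and 1 rose in each when adjusted over the list alone, and none passed in IL-31 (camera adjusted p = 0.000168, 0.000524 and 0.609, and adjusted p = 0.404, 0.545 and 0.975 with an estimated correlation). Extracellular matrix genes had medians of -0.51, -0.39 and -0.24, with 5, 4 and 0 of 44 lower, 1, 1 and 0 when adjusted over the list alone (camera adjusted p = 1.11e-05, 0.00417 and 0.0536, and adjusted p = 0.443, 0.722 and 0.975 with an estimated correlation). Without PBS library 5, the highest of its group in this list, the medians were -0.329, -0.212 and -0.101, and the IL-13 call was lost (camera adjusted p = 0.239). Genes of the gp130 family and STAT3 targets had medians of -0.71, -0.37 and -0.32, with 4, 1 and 0 of 17 lower, 4, 0 and 0 when adjusted over the list alone (camera adjusted p = 0.00351, 0.229 and 0.414), and the IL-4 call was lost without PBS library 5 (adjusted p = 0.0818) and with an estimated correlation (adjusted p = 0.557).

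Chemokines had medians of -0.73, -0.78 and -0.35 in IL-4, IL-13 and IL-31, with 5, 2 and 0 of 25 lower and 1 higher in each, 6, 1 and 0 lower and 1, 0 and 1 higher when adjusted over the list alone (camera adjusted p = 0.0041, 0.024 and 0.609, and adjusted p = 0.404, 0.545 and 0.975 with an estimated correlation), and both calls were lost without PBS library 5 (adjusted p = 0.0685 and 0.242) and that of IL-13 also without IL-13 library 2 (adjusted p = 0.111). Itch mediators and alarmins had 2, 3 and 2 of 21 members higher and 1, 0 and 0 lower, 1, 3 and 2 higher and none lower when adjusted over the list alone (camera adjusted p = 0.25, 0.756 and 0.995). Mast cell markers had medians of -0.24, -0.54 and -0.19 (camera adjusted p = 0.282, 0.0214 and 0.547), and the IL-13 call was lost with an estimated correlation (adjusted p = 0.545) and without any one of PBS libraries 2 and 4 or IL-13 library 2. Camera did not pass for basophil markers (medians -0.28, -0.33 and -0.07), T and innate lymphoid cell markers (-0.14, -0.14 and 0.17), cartilage genes (-0.13, -0.11 and -0.08), melanocyte genes (-0.10, -0.34 and -0.30) or red blood cell genes (-0.88, -0.86 and -0.22). The 2 tested eosinophil markers had medians of -0.26, -0.07 and -0.06 and the 2 tested B and plasma cell markers of -0.03, 0.17 and 0.28, too few for a list test. The cell cycle list had medians of -0.09, 0.30 and 0.01 against PBS with no member past the threshold, and the list's call in IL-13 (camera adjusted p = 0.00019, median 0.177 without IL-13 library 1) was lost with an estimated correlation (adjusted p = 0.722). Stressed keratinocyte genes had medians of -0.65, 0.35 and -0.61 and 2, 3 and 1 of 31 higher, 0, 2 and 1 when adjusted over the list alone (camera adjusted p = 0.507, 0.216 and 0.698). The IL-13 median was -0.42 without IL-13 library 3 and 1.172 without PBS library 5, the libraries with the highest scores of their groups at 3.527 and 2.649. The 17 basal keratinocyte genes had medians of 0.21, 0.22 and 0.08, with 4, 1 and 1 higher and none lower. Siglech, a marker of plasmacytoid dendritic cells, sits in the mast cell list as fixed.

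Mitochondrially encoded transcripts took 4.41 to 5.26% of CPM in PBS libraries 1, 2 and 3 and 3.11 and 3.25% in PBS libraries 4 and 5. The same 3 libraries had the lowest epidermal barrier scores of the 20.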
